A study of Saccharum sp. with 7 samples.

How the data were processed

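Total RNA was isolated with TRIsure reagent and small RNA libraries were built with the TruSeq Small RNA kit, per the labels' protocols. The 5 vegetative libraries each pooled tissue from 3 field-grown plants and were run on the GAIIx, and the 2 cultured libraries were run on the HiSeq, per the series' design text. The authors deposited, for each library, raw read counts per distinct RNA sequence without a header, as judged from the values, which are whole numbers with a different total in each library. Adapter removal, size selection, read filters, any aligner and any genome build are not given in the sources used here. Every listed sequence had 20 to 24 nt and at least 4 reads. The library totals before listing are not given in the sources used here, so RPM means reads scaled to a library total of 1000000 listed reads.

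The lists were tested for gaps. Both cultures held 65534 distinct 24-nt sequences; the lowest 24-nt count was 5 in calli, and suspension cells held 1854 24-nt sequences at 4 reads against 15561 at 5 reads, so the rarest 24-nt sequences of the cultures appear to be missing from the lists. Every listed sequence was kept. Suspension cells had no 22-nt sequence, and the 24-nt sequences of apex stopped partway through the alphabet. If apex had the share past that point seen in the other 4 vegetative libraries, 24-nt reads would make up 70.3% to 75.1% of its reads. Totals and RPM of these 3 libraries are therefore too small and too large by an unknown amount, and results were also computed in the 20-, 21- and 23-nt classes. In the fully listed classes an unlisted sequence is taken to have had at most 3 reads, and 3 reads was the floor used per library for lower bounds of folds. These bounds do not cover the classes listed in part or not at all, such as 22 nt in suspension cells; a family with several unlisted sequences may hold more. The total held 259398 distinct sequences, 602 of them in all 7 libraries and 199928 in 1 library. A few sequences (10 in calli, 6 in suspension cells) contained N and were kept. U is written as T in sequences. No 2 libraries held identical values.

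Sequences were assigned to 32 families from 48 mature plant sequences written down from general knowledge before the data were examined, since no miRNA database or genome was at hand. A sequence belonged to a family when it aligned without gaps over at least 17 nt with at most 1 mismatch and 5′ ends at most 2 nt apart; ties between families were left out. Members of a family with near-identical mature sequences share reads and were not separated, and no precursor or locus was assigned. Reads were found for 28 families. The 9 family lists, and the lists of rRNA, tRNA, adapter and other-organism sequences, were fixed before the data were examined.

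Families were compared between groups with edgeR 4.0.16 (quasi-likelihood test, R 4.3.3) on summed read counts, with the listed total as library size and families with at least 10 reads over all libraries. Single sequences with at least 10 reads in at least 2 libraries were compared with the same test and TMM factors, which lay between 1.51 and 2.13 in vegetative and were 0.273 and 0.282 in cultured libraries. Benjamini-Hochberg adjustment was used with a threshold of 0.05. Standard errors were taken from the fold change and the test's F statistic. Shares and distinct sequence numbers were compared with exact two-sided permutation tests of group means over all 21 splits (scipy 1.17.1). Tissues with 1 library were compared by RPM with exact Poisson intervals, and by the exact interval of the ratio, at a level of 95%. PCR copies are not independent molecules, so intervals cover counting error only; the cultures, with 2264817 and 2684172 reads, have narrower ones than the vegetative libraries, with 249079 to 408928. Replicate numbers only follow the order of deposit, so nothing was paired.

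Named families were those past the threshold, at most 12 per direction, and the most abundant up to 20 in all. In single-library comparisons they were those with intervals that did not overlap, a fold of at least 3 and at least 50 reads in the higher library, at most 8 per direction. Named sequences were the 3 called ones with the largest fold change in each direction among those with a mean of at least 50 RPM in the higher group, and the most abundant one of each library. Alternatives were DESeq2 1.42.0 in place of edgeR, other scalings, other mismatch limits, no low-count filter, thinning to 249079 reads, other denominators and leaving out each library; those added later are named as such.

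The tests were checked on simulated counts with the dispersions estimated here, 1.83 for families and 1.25 for sequences. For families (28), 0 of 4 changed 8-fold and 1 of 4 changed 64-fold were recovered, with no unchanged family called. For sequences (18723), 0 of 67 changed 4-fold, 1 of 67 changed 16-fold and 15 of 66 changed 64-fold were recovered, with no unchanged one called. With the dispersion divided by 10, 4 of 4 families were recovered at each fold, with 1 of 20 unchanged called, and 9 of 67, 47 of 67 and 44 of 66 sequences. Few simulated sequences were changed, baselines came from all libraries together and the minimum of 10 reads was not applied again. In the real data most tested sequences were called, so this check does not give the error rate of those calls.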

Results

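Small RNAs of sugarcane (Saccharum sp., cultivar Q117) were profiled in 7 libraries. The 5 vegetative libraries came from stem apex, internode 3, internode 6, internode 16 and leaf of field-grown plants, each a pool of tissue from 3 plants. The 2 cultured libraries came from calli, which are unorganised masses of cells grown on medium, and from suspension cells, which are grown in liquid. Internodes are numbered down the stem, so a higher number is an older segment. The main question was how the small RNAs of cultured cells differ from those of vegetative tissue. Each tissue was represented by 1 library, so every p-value given for this comparison measures the spread between tissues and not between plants or cultures. Vegetative tissues were sequenced on one instrument type (GAIIx) and cultures on another (HiSeq), so platform and tissue type cannot be told apart.

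The listed reads numbered 269767 in apex, 408928 in internode 3, 249079 in internode 6, 310826 in internode 16, 260189 in leaf, 2264817 in calli and 2684172 in suspension cells. Only sequences of 20 to 24 nt with at least 4 reads were listed, and this floor corresponded to between 9.78 and 16.1 RPM (reads scaled to a library total of 1000000 listed reads) in vegetative libraries and to 1.49 and 1.77 RPM in the cultures. Several length classes were listed in part. No 22-nt sequence was listed for suspension cells, calli and suspension cells each held 65534 distinct 24-nt sequences, and the 24-nt sequences of apex ended at ATGAGACGGCTGTAAACTTATAGC in alphabetical order. In the other 4 vegetative libraries, between 51.0% and 61.7% of 24-nt reads lay past that sequence. The 20-, 21- and 23-nt classes showed no such break in any library.

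Reads of 21 nt and 24 nt were the most abundant classes in all 7 libraries. The 21-nt class, which holds most miRNAs, made up 18.1% of reads in apex, 26.8% in internode 3, 37.2% in internode 6, 39.6% in internode 16 and 51.2% in leaf, against 35.8% in calli and 59.4% in suspension cells. The 24-nt class, which holds the siRNAs associated with DNA methylation, took 53.7% in apex, 47.6% in internode 3, 28.8% in internode 6, 27.5% in internode 16, 32.6% in leaf, 40.7% in calli and 31.4% in suspension cells. The 22-nt class was largest in internode 6, at 26.9%, and lowest among the vegetative libraries in leaf, at 10.2%. For 21 nt the group means were 34.6% ± 12.7 (SD, n = 5) in vegetative and 47.6% ± 16.7 (SD, n = 2) in cultured libraries, with an exact two-sided permutation p of 0.381. For 24 nt they were 38.0% ± 11.9 (SD, n = 5) and 36.1% ± 6.60 (SD, n = 2), with an exact permutation p of 0.857. For 22 nt they were 17.5% ± 6.67 (SD, n = 5) and 5.61% ± 7.94 (SD, n = 2), with an exact permutation p of 0.190, and the cultured mean includes the unlisted class of suspension cells as 0. With 21 splits of 5 against 2, the smallest p this test can give is 0.0952, so none of the 7 measures compared in this way could pass 0.05; their Benjamini-Hochberg adjusted values lay between 0.667 and 1. The 24-nt difference of -1.96 percentage points became 6.62 without apex and suspension cells, and the 21-nt difference of 13.0 percentage points became -2.89, an alternative chosen after the data were examined.

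**Figure D1:**
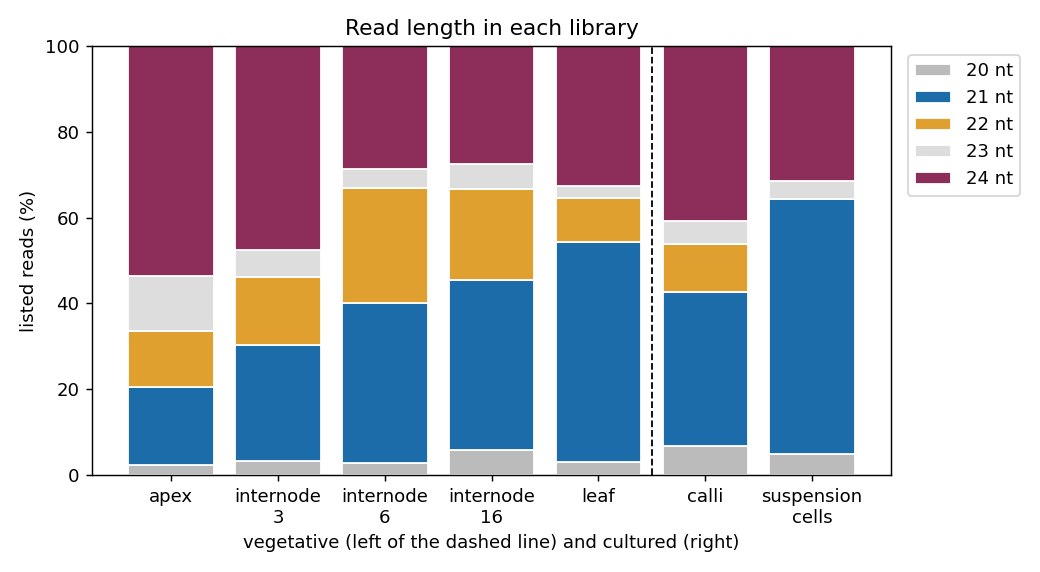
Stacked bars give the share of listed reads (%) of each length from 20 to 24 nt in each library, with the 5 vegetative libraries left of the dashed line and the 2 cultured ones right of it. The 21-nt share is lowest in apex (18.1%) and highest in suspension cells (59.4%), where the 22-nt class is not listed; the 24-nt classes of apex, calli and suspension cells are listed in part.

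Uracil was the leading 5′ base of 21-nt reads in every library, as is usual for plant miRNAs. Its share was 62.1% ± 7.64 (SD, n = 5) in vegetative and 72.5% ± 14.4 (SD, n = 2) in cultured libraries, from 82.7% in calli to 62.4% in suspension cells, and the groups were not distinguished (exact permutation p = 0.286). Adenine at the 5′ end took 52.9% of 24-nt reads in internode 3, 46.6% in internode 6, 45.3% in internode 16, 57.9% in leaf, 49.6% in calli and 55.7% in suspension cells. Apex stood at 100% because of where its list ended. With apex included the exact permutation p was 1, and without apex the difference of -7.92 percentage points became 1.95.

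The listed conserved miRNA families and tasiR-ARF made up 8.32% of reads in apex, 13.9% in internode 3, 18.7% in internode 6, 14.7% in internode 16 and 29.998% in leaf, and 22.8% in calli and 9.05% in suspension cells. The group means of 17.1% ± 8.09 (SD, n = 5) and 15.9% ± 9.72 (SD, n = 2) differed by less than the spread between tissues (exact permutation p = 0.952). The direction of the difference of -1.22 percentage points turned to 4.76 when 5′ ends up to 4 nt from the reference were accepted, which brings in the most abundant sequence of suspension cells, to 1.997 without leaf and to 5.65 without suspension cells.

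Cultured cells differed from vegetative tissue in 8 of 28 tested families. Rising in culture were miR528, a grass family, miR408, miR397, miR156 and tasiR-ARF. miR399, miR162 and miR437 fell. miR528 averaged 13366 ± 17059 RPM (SD, n = 2) in culture and was listed in 1 of 5 vegetative libraries, leaf, at 15.4 RPM (log2 fold change 12.08, SE 2.34, edgeR adjusted p = 0.0128). Its mean rests on suspension cells, at 25428 RPM against 1303 RPM in calli. Leaving out 1 library gave a log2 fold change of 8.70 to 16.75, lowest without suspension cells, where the call was lost (edgeR adjusted p = 0.0636). miR156 averaged 31874 ± 27771 RPM (SD, n = 2) in culture and 418 ± 648 RPM (SD, n = 5) in vegetative tissue, a 76.2-fold difference of means (edgeR log2 fold change 6.25, SE 2.004, adjusted p = 0.0448). Leaving out 1 library gave a log2 fold change of 4.87 to 7.86, lowest without calli. The call was lost without either culture or any of the 3 internodes (edgeR adjusted p up to 0.137) and with 2 mismatches allowed (0.0941), and DESeq2 gave miR156 no adjusted p. miR162, which targets the mRNA of Dicer-like 1, fell from 2237 ± 886 RPM (SD, n = 5) to 21.1 ± 14.9 RPM (SD, n = 2), with an edgeR log2 fold change of -6.72 (SE 1.82, adjusted p = 0.0278). The miR162 call was kept under 11 other settings and lost under 7. Among the latter were TMM factors (edgeR adjusted p = 0.0669) and the floor applied again after thinning (0.0805).

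Among the copper-responsive families, 3 of 4 rose and 1 did not pass the test, and all 4 rose when p-values were adjusted over the list alone. These families target mRNAs of copper proteins such as laccases, plantacyanins and superoxide dismutase. Besides miR528, miR408 averaged 1339 ± 499 RPM (SD, n = 2) in culture and was listed among vegetative libraries in leaf alone, at 34.6 RPM (edgeR log2 fold change 7.60, SE 2.11, adjusted p = 0.0278, and 7.15 to 13.43 leaving out 1 library). The miR408 call was lost under 6 other settings (edgeR adjusted p up to 0.0715) and kept under 12. With 5′ ends at most 2 nt apart, miR397 was listed in no vegetative library and averaged 34.5 ± 7.01 RPM (SD, n = 2) in culture. This was at least 3.34-fold above the level of 3 reads per vegetative library (edgeR adjusted p = 0.0278). With 5′ ends up to 4 nt apart, its edgeR log2 fold change was 6.75 (SE 1.39, adjusted p = 0.00969). A further sequence, TTGACTGCAGCGTTGATGAGC, is joined to miR397 when 5′ ends up to 4 nt apart are accepted, and was chosen by rule as the most abundant of suspension cells. It stood at 56440 RPM in calli and 58665 RPM in suspension cells against 264 ± 248 RPM (SD, n = 5) in vegetative tissue, where it was listed in all 5 libraries (edgeR log2 fold change over tags 10.24, SE 1.67, adjusted p = 7.0e-06). This fold is larger than the ratio of the means because the test over tags used TMM factors. miR398 stood at 2011 ± 171 RPM (SD, n = 2) in culture and 59.7 ± 110 RPM (SD, n = 5) in vegetative tissue, with an edgeR adjusted p of 0.124 over all families. It was listed in 2 vegetative libraries, leaf at 254 RPM and internode 16 at 45.0 RPM. Under 3 other settings miR398 passed, among them TMM factors (edgeR adjusted p = 0.0317) and the miRNA total (0.0328), and under 13 it did not.

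In the phase change list, which holds families that target SPL and AP2 transcription factors, 1 of 3 measured members rose, miR156, and 2 did not pass; the same count held adjusted over the list alone. miR529 was at 1799 ± 1802 RPM (SD, n = 5) in vegetative and 71.1 ± 101 RPM (SD, n = 2) in cultured libraries (edgeR adjusted p = 0.218), and passed with DESeq2 (adjusted p = 0.0322). The fourth member, miR535, had no listed read. Of the small RNA machinery families, miR162 fell and miR168, which targets the mRNA of ARGONAUTE 1, did not pass, at 27639 ± 17115 RPM (SD, n = 5) in vegetative and 9726 ± 815 RPM (SD, n = 2) in cultured libraries (edgeR adjusted p = 0.403); adjusted over the list alone, 1 fell. Of 4 nutrient-responsive families, miR399, which acts in phosphate homeostasis, fell and 3 did not pass, and adjusted over the list alone 1 fell. It was listed in all 5 vegetative libraries at 107 ± 90.7 RPM (SD, n = 5) and in neither culture, at least 87.5-fold lower there if the unlisted 22-nt class of suspension cells holds none (edgeR adjusted p = 0.0229). miR827, of the same list, had means of 327 ± 303 RPM (SD, n = 5) and 1200 ± 238 RPM (SD, n = 2) and an edgeR adjusted p of 0.266, and passed with TMM factors (0.0260). Of 4 measured grass or monocot families 1 rose (miR528) and 1 fell, and the same counts held adjusted over the list alone. The family that fell was miR437, from 112 ± 92.9 RPM (SD, n = 5) to 3.75 ± 1.55 RPM (SD, n = 2), with an edgeR log2 fold change of -4.85 (SE 1.60, adjusted p = 0.0448). This call was lost in 12 of 18 other settings, among them the miRNA total (edgeR adjusted p = 0.0777), 5′ ends up to 4 nt apart (0.0801), without calli (0.223, the highest) and without suspension cells (0.169). miR444, whose targets are MADS-box genes, was at 860 ± 741 RPM (SD, n = 5) and 274 ± 324 RPM (SD, n = 2) and did not pass (edgeR adjusted p = 0.433). miR1432 had no listed read.

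Of 5 auxin response members, tasiR-ARF rose and 4 did not pass, and none passed adjusted over the list alone. tasiR-ARF, a trans-acting siRNA against auxin response factor mRNAs, was listed in no vegetative library and at 68.4 RPM in calli and 2.24 RPM in suspension cells, on average at least 3.42-fold above 3 reads per vegetative library (edgeR adjusted p = 0.0448). Its mean rests on calli, since the value in suspension cells lies below the vegetative floor, and its call was lost in the 20-, 21- and 23-nt classes (edgeR adjusted p = 0.0859) and with 5′ ends up to 4 nt apart (0.0799); over alternatives the adjusted p reached 0.145. miR167 was at 23215 ± 18213 RPM (SD, n = 2) in culture and 1081 ± 1393 RPM (SD, n = 5) in vegetative libraries (edgeR adjusted p = 0.176), and passed with TMM factors (0.0486). miR160 was at 230 ± 142 RPM (SD, n = 2) and 410 ± 805 RPM (SD, n = 5) (edgeR adjusted p = 0.783). None of the 6 meristem and organ patterning families and none of the 3 MYB, TCP and GRF families passed, over all families or adjusted over the list alone, in the main edgeR test; at an unadjusted p under 0.05, 10 of all 28 families did. Under other settings 4 of their members passed: miR159 and miR171 with TMM factors (edgeR adjusted p = 0.0252 and 0.0486), miR166 without calli (0.0491) and miR394 with DESeq2 (0.0140). Over all alternatives their adjusted p reached 0.459, 0.766, 0.982 and 0.917. The abundant members differed widely within a group. miR166, against HD-ZIP III transcription factors, was at 98443 ± 69985 RPM (SD, n = 5) and 16560 ± 22925 RPM (SD, n = 2), with an edgeR adjusted p of 0.266. miR319, against TCP factors, was at 19930 ± 11924 RPM (SD, n = 5) and 38093 ± 53207 RPM (SD, n = 2), with an edgeR adjusted p of 0.751. miR396, against growth-regulating factors, was at 13019 ± 11171 RPM (SD, n = 5) and 8517 ± 8496 RPM (SD, n = 2), with an edgeR adjusted p of 0.783. miR164, against NAC factors, was at 662 ± 747 RPM (SD, n = 5) and 548 ± 76.5 RPM (SD, n = 2), with an edgeR adjusted p of 0.924. miR159, against GAMYB-like factors, was at 3229 ± 2358 RPM (SD, n = 5) and 11464 ± 843 RPM (SD, n = 2), with an edgeR adjusted p of 0.266. Neither family that triggers reproductive phased siRNAs, miR2118 and miR2275, had a listed read, but the 22-nt class of suspension cells was not listed.

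With unlisted values of the lower group set at 3 reads, both cultures lay above all vegetative libraries in 9 families and below all of them in 6, where chance gives 9.52% of families without overlap, or 2.67 of 28. Families share library totals and the platform split, so they are not independent and the excess is not a test. For miR166 and miR529, apex was the lowest vegetative library, at 41065 and 211 RPM against 32770 and 142 RPM in calli. Both lists are partial, so these RPM are too large by unknown amounts. In the 20-, 21- and 23-nt classes calli stayed below apex, at 68088 against 123408 and 296 against 635 RPM. Of the 9 families, miR169 and miR827 no longer lay above all vegetative libraries in these classes. Suspension cells stood at 47.8 and 1505 RPM there, against 62.7 and 1631 RPM in internode 16. The count of 8 families rested on few libraries: it was 2 without calli, and 0 without suspension cells, when 8 families had an unadjusted edgeR p under 0.05. It was 2 without internode 3, 3 without internode 6 and 2 without internode 16. DESeq2 called 11, of which 5 rose. Of these 11, 7 were among the 8 main calls, and of the 12 calls with TMM factors 6 were. Scaling by TMM factors moved the median log2 fold change of all families from 0.10 to 2.63 and gave 11 of 12 calls higher in culture; miR162 and miR437 stayed lower but did not pass there (edgeR adjusted p = 0.0669 and 0.190, over alternatives up to 0.131 and 0.223). With the miRNA total as library size, 6 of 8 calls were higher. With reads thinned to the smallest total and the floor of 4 reads applied again, an alternative chosen after the data were examined, miR528, miR408 and miR156 passed and the other 5 calls did not.

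**Figure D2:**
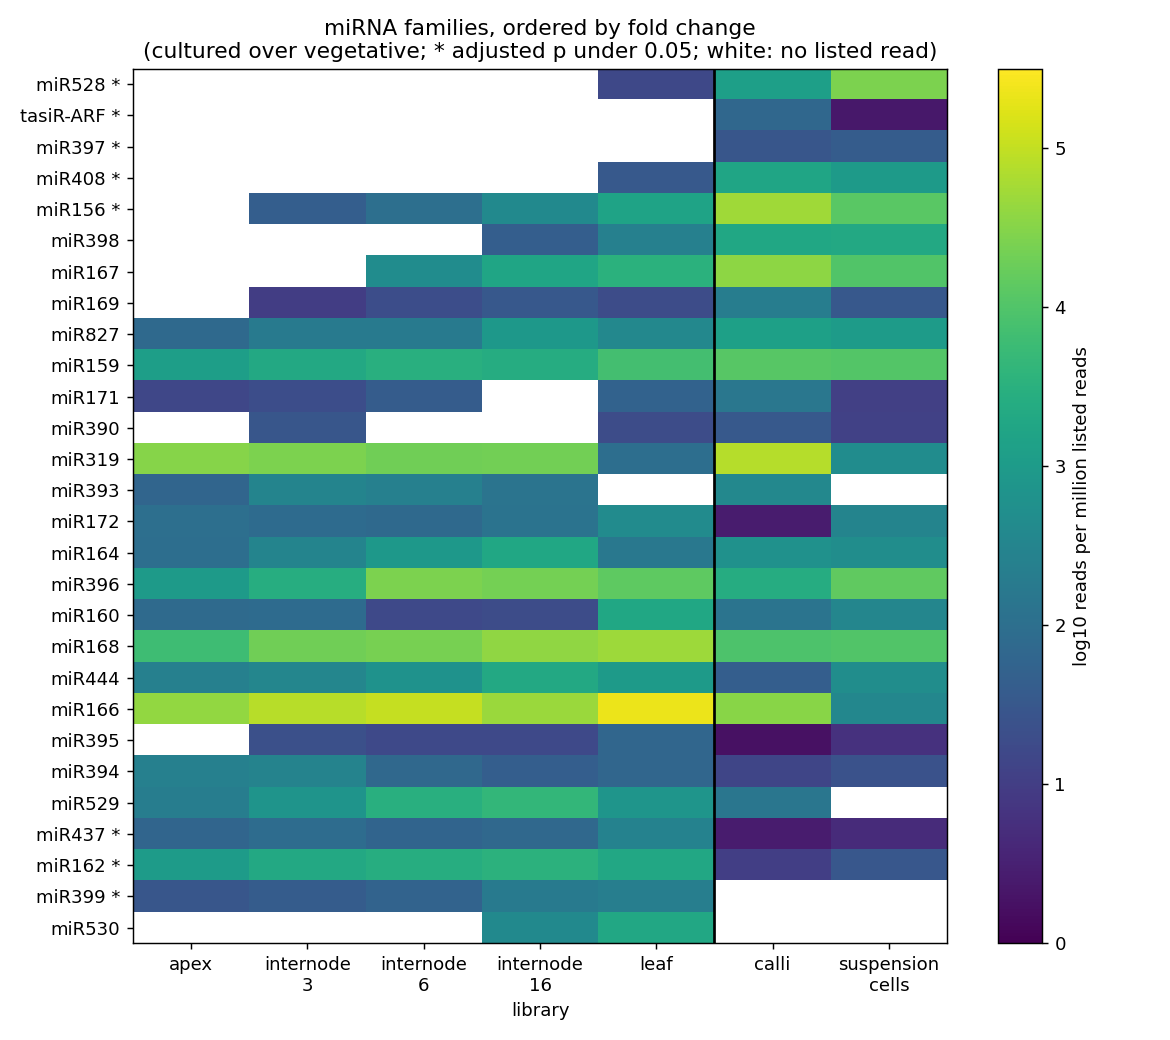
The heat map gives log10 RPM of 28 families in 7 libraries, from the highest to the lowest log2 fold change of cultured over vegetative libraries, with white where no read was listed and a star at the 8 families with an edgeR adjusted p under 0.05. miR528 reaches 25428 RPM in suspension cells and is listed in leaf alone among vegetative libraries, whereas miR162 lies between 1027 and 3410 RPM in vegetative libraries and at 10.6 and 31.7 RPM in culture.

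Without any annotation, 15695 of 18950 sequences tested differed between the groups (edgeR adjusted p under 0.05), 11879 of them higher in culture. TGAAGCTGCCAGCATGATCTA, a miR167 sequence, led the higher ones at 16214 RPM in calli and 8909 RPM in suspension cells and was listed in no vegetative library, at least 1215-fold higher on average (edgeR adjusted p = 9.3e-07). GCTCACTCTCTATCTGTCAGC and TGGGAAGCAATTCGTCGAACA, assigned to no listed family, followed, at least 674-fold and 291-fold higher on average, with edgeR adjusted p-values of 3.0e-06 and 2.3e-05. The former stood at 11994 RPM in calli and 1950 RPM in suspension cells. The latter stood at 24.7 and 5984 RPM, so its mean rests on suspension cells. Of those lower in culture, TTCGGACCAGGCTTCATTCCC, a miR166 sequence, averaged 28341 ± 43150 RPM (SD, n = 5) in vegetative libraries and was listed in neither culture (edgeR adjusted p = 0.000215). The 22-nt sequences TACCGAGTAGGACTGACACAAG and TACCGAGTAGAACTGACACAAG reached 13610 and 8363 RPM in internode 6 and were listed in neither culture, but the 22-nt class of suspension cells was not listed at all (edgeR adjusted p = 0.00198 and 0.00928). The most abundant sequence was TCGGACCAGGCTTCATTCCCC (miR166) in apex, internode 3 and internode 6, at 32647, 55474 and 60981 RPM. It was TCGCTTGGTGCAGATCGGGAC (miR168) in internode 16 at 26919 RPM, TTCGGACCAGGCTTCATTCCC in leaf at 104920 RPM and TTGGACTGAAGGGTGCTCCCT (miR319) in calli at 71125 RPM.

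The count of sequences depended on the listing. Of the 11879 sequences higher in culture, 87.9% were listed in no vegetative library, and 50.2% had a cultured mean below 9.78 RPM, the lowest vegetative floor. Of 3522 sequences with at least 50 RPM in 2 libraries, 1066 passed, with 328 higher and 738 lower in culture, and after thinning all libraries to 249079 reads 443 of 5097 passed, with 353 higher. No sequence passed without calli or without suspension cells, when 1786 and 1551 had an unadjusted edgeR p under 0.05.

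After thinning to 249079 reads, distinct sequences numbered 74779 in calli and 70381 in suspension cells. They numbered 23418 in apex, 29762 in internode 3, 14492 in internode 6, 20140 in internode 16 and 14131 in leaf. The means were 72580 ± 3110 (SD, n = 2) and 20389 ± 6539 (SD, n = 5), and the exact permutation p of 0.0952 is the smallest possible. Thinned cultures keep sequences with under 4 reads, which the vegetative lists lack, so these counts cannot tell which group held more. With the floor of 4 reads applied again to every library after thinning, the direction turned. This setting cannot tell either, since it takes more reads from the thinned cultures than from the vegetative lists, which were floored before. Internode 6, the smallest library, lost no sequence. Calli then held 8754 and suspension cells 10505 sequences, and the vegetative libraries between 13454 and 21138.

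The sequences of the groups also ended differently. Among distinct 21-nt sequences, C was next to last in 48.1% ± 2.61 (SD, n = 5) in vegetative and 21.1% ± 1.33 (SD, n = 2) in cultured libraries, and G in 22.3% ± 1.78 (SD, n = 5) and 43.2% ± 0.838 (SD, n = 2). Among distinct 24-nt sequences, C was next to last in 40.7% ± 1.79 (SD, n = 5) and 14.2% ± 1.58 (SD, n = 2). Fragments of 5S rRNA were listed in no vegetative library and at 1455 RPM in calli and 2534 RPM in suspension cells. These sums cover 243 distinct sequences, with 3296 reads in calli and 6802 in suspension cells. Many may lie near or under the vegetative listing floor, so a difference between the groups is not shown. Fragments from the 5′ end of glycine tRNA stood at 97.9 ± 212 RPM (SD, n = 5) in vegetative libraries and 6001 ± 2125 RPM (SD, n = 2) in culture, and those of the tRNA 5′ end listed without an amino acid at 0 and at 2896 ± 2591 RPM (SD, n = 2). Histidine tRNA fragments averaged 31.3 RPM in vegetative and 12.4 RPM in cultured libraries. Arginine and aspartate tRNA fragments were listed only in culture, at up to 43.6 RPM over 4 sequences and 4.10 RPM, the latter under the vegetative floor. No read matched 5.8S rRNA, plastid 4.5S rRNA, the 3′ adapter or the 9 animal and dicot miRNAs searched for.

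**Figure D3:**
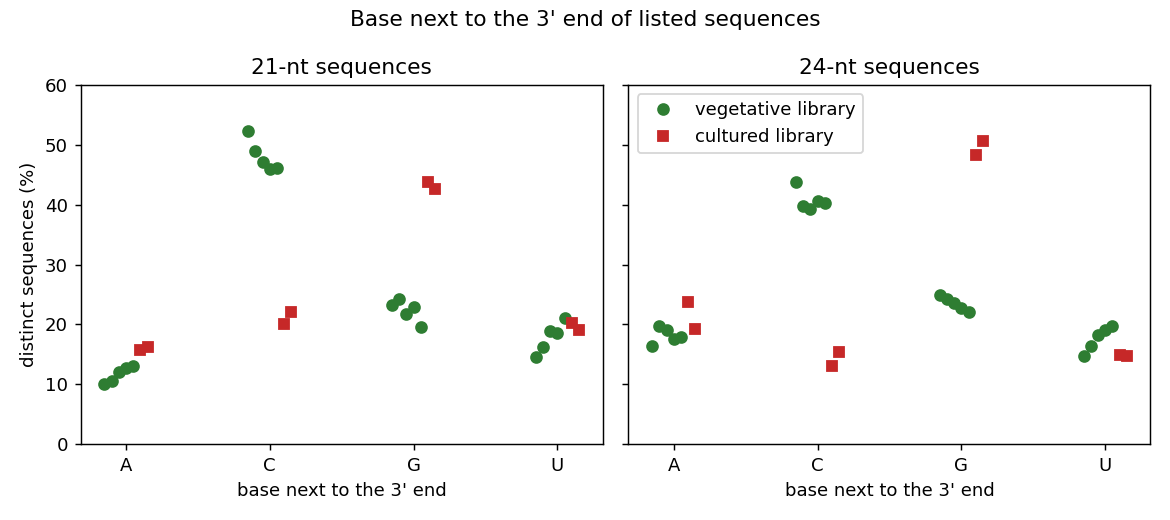
Points give the share of distinct sequences (%) with each base next to the 3′ end, for 21-nt (left) and 24-nt (right) sequences, as circles for the 5 vegetative and squares for the 2 cultured libraries. C is at 45.9% or above in vegetative and at 22.04% or below in cultured libraries for 21 nt.

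Calli and suspension cells, compared as 1 library each with no replicate, differed by at least 3-fold, with exact 95% Poisson intervals that did not overlap, in 14 families, 10 higher in calli and 4 higher in suspension cells. miR319 stood at 75716 RPM in calli and 471 RPM in suspension cells, a ratio of 161 (95% interval 152 to 170). miR166 was 93.6-fold higher in calli (95% interval 87.7 to 99.9). miR393, which targets auxin receptor mRNAs, and miR529 were listed in calli at 361 and 142 RPM and not in suspension cells, at least 323-fold and 127-fold higher, with the same limit on the unlisted 22-nt class. tasiR-ARF was 30.6-fold, miR171 14.0-fold, miR169 6.55-fold and miR156 4.21-fold higher in calli. In suspension cells, miR172, which targets AP2-like factors, was 117-fold higher (95% interval 53.3 to 319) on 6 reads in calli and 829 in suspension cells. miR528 was 19.5-fold (95% interval 18.8 to 20.2), miR444 11.2-fold (9.13 to 13.8) and miR396 5.79-fold higher (5.63 to 5.95). The intervals cover counting error only. With the miRNA total as denominator, 14 families passed, 8 of them higher in suspension cells. miR319 was then 63.9-fold and miR166 37.1-fold higher in calli, and miR169 at 2.60-fold and miR156 at 1.67-fold no longer passed. In the 20-, 21- and 23-nt classes 13 passed, 9 of them higher in calli.

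Along the stem, the families that differed by at least 3-fold mostly stood higher in the older internode, again with 1 library per tissue and no test. From internode 3 to internode 16, 10 families differed by at least 3-fold, 9 of them higher in internode 16. By less than 3-fold, the 2 most abundant families of internode 3 stood lower in internode 16. These were miR166, at 83086 and 47596 RPM, and miR319, at 26415 and 21073 RPM. In the 20-, 21- and 23-nt classes 11 families passed, 9 higher and 2 lower (miR394 and miR393), and miR396 was 5.82-fold higher. miR396 was at 2707, 25803 and 22238 RPM in internodes 3, 6 and 16, and 8.21-fold higher in internode 16 than in internode 3 (95% interval 7.71 to 8.76). miR167 was not listed in internode 3 and stood at 478 RPM in internode 6 and 1676 RPM in internode 16, at least 228-fold higher there; in the 20-, 21- and 23-nt classes it was at least 47.9-fold higher than in internode 3. miR530 was listed in internode 16 alone of the 3, at 412 RPM, at least 56.1-fold above internode 3. miR156 was at 44.0, 100.4 and 405 RPM, miR529 at 714, 2919 and 4424 RPM, miR164 at 306, 859 and 1885 RPM, miR444 at 337, 630 and 2075 RPM and miR399 at 39.1, 56.2 and 187 RPM. miR394, which targets an F-box gene, was 6.30-fold lower in internode 16 than in internode 3 (95% interval of the ratio 3.61 to 11.9). Between internodes 3 and 6, 4 families passed (miR167, miR396 and miR529 higher and miR394 lower in internode 6), and in the 20-, 21- and 23-nt classes 3 passed, without miR167 on 43 reads. Between internodes 6 and 16, 6 passed, all higher in internode 16 and including miR827 at 181 and 836 RPM, and 3 passed in the 20-, 21- and 23-nt classes. In apex, beside these, miR396 stood at 1005 RPM, miR529 at 211 RPM and miR164 at 96.4 RPM, and in leaf at 13340, 726 and 161 RPM.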

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

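The tests on partial length classes, on abundant sequences and on platform were chosen only after the result was seen. Of 33 measures examined over the 5 vegetative libraries, 10 had one library far from the other 4, against 1.65 at a rate of 1 in 20. That rate assumes normally distributed replicates, whereas these are RPM and shares of 5 different tissues, and the measures are not independent. Measures with no listed vegetative read could not be flagged. The excess is therefore not a test. For 2 of the 10, miR408 and miR528, the listing floor fixes the gap, since the other 4 libraries have no listed read, and without them 8 remain. Leaf stood apart in 7 of the 10, these 2 included. Leaf was highest for miR160 at 1849 RPM (next library 83.1), miR156 at 1541 RPM (next 405), miR437 at 277 RPM (next 88.0) and miR398 at 254 RPM (next 45.0). It was the only vegetative library with listed reads of miR408, at 34.6 RPM, and of miR528, at 15.4 RPM or 4 reads, the least that is listed. The miR166 sequence TTCGGACCAGGCTTCATTCCC reached 104920 RPM in leaf, against 15395 RPM in the next library. Internode 6 stood apart for TACCGAGTAGGACTGACACAAG, at 13610 RPM, and TACCGAGTAGAACTGACACAAG, at 8363 RPM. Apex stood apart for the 5′ A share of 24-nt reads, at 100%, where its list ended within the sequences that begin with A.

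The 3′ ends of listed sequences differed between vegetative and cultured libraries, with C next to last far more often in vegetative ones. Partial length classes are argued against: in the fully listed 21-nt class, the lowest vegetative share of distinct sequences exceeded the highest cultured one by 23.9 percentage points. A few abundant sequences do not account for it either, since the gap over distinct 24-nt sequences was 23.9 percentage points. Trimming shifted by 1 base is argued against by miR159, miR168 and miR396: reads starting at the first mature base were most often 21 nt in all 7 libraries for 3 of the 3 families. Sequencing platform or library batch may be a source and cannot be told apart from tissue type, since 0 tissues were run on both platforms, and a biological difference between cultured and vegetative tissue stays open and untested.

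The family differences between groups were weighed against the same technical features. Taking out the fold predicted from the last 2 bases left 8 of the 8 called families beyond 2 SE in the same direction. The largest absolute log2 fold so predicted for a called family was 1.31. Thinning to the smallest total left 8, and the 20-, 21- and 23-nt classes left 8. A bar of 2 SE is lower than that of the calls. By edgeR adjusted p, 7 of the 8 still passed after thinning and 7 in those classes. The last 2 bases, depth and partial classes thus do not account for the folds as the whole cause. Predicted and observed log2 folds still had a Spearman rho of 0.49 across the 28 families, which are not independent replicates, so a part from the 3′ ends stays open. Applying the listing floor again after thinning left 7 beyond 2 SE. miR397, with 5′ ends at most 2 nt apart, was no longer measured, and its call under that rule may rest on the floor. With 5′ ends up to 4 nt apart, which brings in a sequence listed in all 5 vegetative libraries, miR397 also passed (edgeR adjusted p = 0.00969). miR162 kept its fold (log2 -6.72, SE 1.82, before and -6.76, SE 2.46, after) but lost its call with the wider error. The calls of miR399 (-9.62, SE 2.15, and -7.73, SE 3.18) and tasiR-ARF (8.03, SE 2.22, and 5.73, SE 2.73) ended with a smaller fold and a wider error, and that of miR437 (-4.85, SE 1.60, and -7.74, SE 3.17) with a wider error alone. Sequencing platform or library batch, with any bias beyond the last 2 bases, cannot be told apart from tissue type (0 tissues on both platforms), which itself stays open.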

How the results depend on the processing

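Alternatives that concern partial length classes, 5′ ends up to 4 nt apart, the floor applied again and sequences of at least 50 RPM were chosen after the data were examined. Depth limits the vegetative libraries, where a sequence under 9.78 to 16.1 RPM is not listed. No pseudocount alternative was run, since the values are counts, and 20 to 25 nt as denominator moves nothing, since all listed reads have 20 to 24 nt. Where 1 culture is left out, edgeR assumes that the lone library varies like the vegetative ones, and shares are values with no test. The cause was not tested for the changes below unless stated. The cultured minus vegetative difference of the 24-nt share (-1.96 percentage points) was 1.97 over distinct sequences, 1.88 without the 10 most abundant sequences of each library and 6.62 without apex and suspension cells; leaving out 1 library gave -6.63 to 2.71. That of the 21-nt share (13.0) was -2.89 without apex and suspension cells and 1.23 to 24.8 leaving out 1 library, lowest without suspension cells. Leaving out 1 library gave -17.5 to -6.26 for the 22-nt share (-11.9) and 0.26 to 20.6 for the 5′ U share of 21-nt reads (10.4). That of the miRNA share (-1.22) was 4.76 with 5′ ends up to 4 nt apart and -8.09 to 5.65 leaving out 1 library, positive without leaf and without suspension cells. That of the 5′ A share of 24-nt reads (-7.92) was -11.7 to 1.95 leaving out 1 library, positive without apex, whose list holds only A. That of distinct sequences (52191) was -6656 with the floor of 4 reads applied again. Flooring after thinning takes more reads from the cultures than from the vegetative libraries, so neither sign shows which group held more. The count of called families (8) was 4 with 2 mismatches allowed and 3 with the floor applied again, and 0 to 8 leaving out 1 library; DESeq2 called 11 and TMM scaling gave 12. Called sequences (15695) numbered 36745 of 59470 without a low-count filter, where more sequences are tested, and, where fewer are, 443 after thinning, 4430 in the 20-, 21- and 23-nt classes, 1066 at 50 RPM in 2 libraries and 458 with both limits, and 0 to 15348 leaving out 1 library. Families differing between internodes 6 and 16 (6) numbered 3 in the 20-, 21- and 23-nt classes. Of named families, none past the threshold changed direction under these alternatives. Below it, TMM scaling turned the log2 fold change of miR168 to 1.003, miR396 to 1.87, miR444 to 0.86, miR164 to 2.27 and miR160 to 1.62, and the miRNA total turned miR396 to 0.23 and miR160 to 0.40. Leaving out 1 library gave -5.40 to 1.93 for miR319 and -2.38 to 0.16 for miR396, both turned without calli, -0.55 to 0.62 for miR164, turned without internode 16, and -1.66 to 2.19 for miR160, turned without leaf. Over all named families, sequences and single-library folds, 251 of the values under other settings kept their side of the threshold or stayed within their interval, 21 fell short of it, 6 passed it, 37 moved beyond their interval and 7 reversed. Leaving out 1 library, 130 kept their side, 39 fell short, 2 passed and 4 reversed. No paired analysis was possible because replicate numbers are only the order of deposit and the groups share no label that pairs libraries.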

Other observations

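The comparisons and sequences in this part, and the tests on counting error and on a 5′ shift of reads, were chosen only after the values were seen. Leaf and internode 16, 1 library each, differed by at least 3-fold in 10 families, 7 of them higher in leaf. miR160, which targets auxin response factor mRNAs, was 95.8-fold higher in leaf (95% Poisson interval of the ratio 43.7 to 262), and miR166 4.502-fold higher (4.42 to 4.58), at 214279 RPM. miR319 was 219-fold lower in leaf than in internode 16 (95% interval of the ratio 148 to 339), at 96.1 RPM, and apex and internodes 3 and 6 held between 20672 and 31394 RPM. miR164 was 11.7-fold and miR529 6.09-fold lower in leaf. With the miRNA total as denominator, 8 families passed, 1 higher in leaf (miR160, 47.04-fold) and 7 lower, and miR166, at 2.21-fold, no longer did. Between apex and internode 3, 4 families passed the same rule, but 2 passed in the 20-, 21- and 23-nt classes and 0 with the miRNA total.

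CCCGCCTTGCACCAAGTGAAT, assigned to no listed family, stood at 11897 ± 4285 RPM (SD, n = 5) in vegetative and 98.1 ± 31.4 RPM (SD, n = 2) in cultured libraries (edgeR log2 fold change over tags -4.39, SE 2.06, adjusted p = 0.0507). With the TMM factors of that test, this fold is smaller in size than the ratio of the means. The miR168 sequence TCGCTTGGTGCAGATCGGGAC stood at 21823 ± 13494 RPM (SD, n = 5) and 8939 ± 989 RPM (SD, n = 2). Its edgeR log2 fold change over tags was 1.22 (SE 1.41, adjusted p = 0.426), opposite in direction to these means because the test over tags used TMM factors. For miR167, the 22-nt TGAAGCTGCCAGCATGATCTGA was listed in internode 6, internode 16 and leaf, at 177, 875 and 2083 RPM, and at 18570 RPM in calli.

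The miR166 sequence that starts 1 base upstream, TTCGGACCAGGCTTCATTCCC, had a ratio to the common one, TCGGACCAGGCTTCATTCCCC, of 0.0810 in internode 3, 0.225 in internode 6 and 0.907 in internode 16, with 0.0971 in apex and 1.62 in leaf; it was listed in neither culture. Counting error is argued against, since the lower 95% bound in internode 16 exceeded the upper bound in internode 3 by 0.787. The 3′ end bases are argued against too: the ratio of other 21-nt reads ending in CCC to those ending in CCCC was higher in internode 16 by 0.515 on the log2 scale, against 3.49 for the miR166 forms. A general 5′ shift of reads is argued against as the whole cause. Of 8 other families with at least 100 reads at the reference start in internode 16, 7 had an upper 95% bound of the upstream ratio there of at most 0.0986, against 0.907 for miR166, with unlisted upstream sequences set at 3 reads for each length. miR168 had 0 listed upstream reads against 11610 at the reference start. The exception was miR319, at 0.171 in internode 3 and 0.371 in internode 16, so a shift shared by some families stays open. miR156 had too few reads at the reference start to enter the count. Its upstream reads outnumbered those at that start in both internodes, with 70 against 13 in internode 16 and 9 against 0 in internode 3. A high upstream level is thus not particular to miR166, but a rise along the stem is not shown for miR156. A median over families, planned before the result was seen, was not used, since miR319 alone could enter it (log2 change 1.12). A difference in use of miR166 precursors between tissues may be involved, but with 1 library per tissue and no genome it was not tested.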
